A study of Mus musculus with 8 samples.

How the data were processed

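RNA was measured in the dorsal hippocampus of male C57BL/6J mice aged 10 to 12 weeks. Per the labels' protocols, an adeno-associated virus of type AAV2/9 was injected into this region. It carried either a U6-driven short hairpin RNA against Acss2 together with EGFP (the knockdown vector) or EGFP without a hairpin cassette (the control vector). After 3 weeks, mice either stayed in the home cage (untrained) or explored an arena with 3 objects in 3 trials of 6 min (trained), and trained mice were killed 30 min later. Polyadenylated RNA was made into libraries with the ScriptSeq v2 kit and sequenced on a NextSeq 500, per the labels' protocols. There were 4 groups of 2 libraries each, 8 in all. The labels do not say whether a library came from 1 mouse or several, so p-values here measure only the spread between libraries, part of which may be technical.

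Per the submitters' processing notes, the tools named are bcl2fastq 02.14.01.07, STAR 2.3.0 (an aligner), HTSeq 0.6.1 (a read counter), DESeq and bedtools, and the build is mm10. The versions of the last pair, the gene annotation and the strand setting of the counting are not given in the sources used here. The values that the authors deposited are a normalized signal per gene and library. Every deposited value was a whole multiple of its library's smallest value, to a relative tolerance of 1e-06, in 100% of values, so each was read as a read count divided by 1 size factor per library. These values are called normalized read counts below. The table held 24503 entries, of which 5 were summary entries of the counter and 24498 were genes; 5869 genes had no read in any library. The summary entries stayed out of library sizes and tests. Of all reads, between 16.4% and 20.3% per library fell in no gene, between 10.6% and 13.8% did not align uniquely, between 2.76% and 7.86% did not align, and between 0.379% and 0.424% were ambiguous between genes.

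Depth differed widely. Reads in genes came to 7552478 and 9863728 in the untrained control libraries (eGFP.254 and eGFP.268, named here by the end of the deposited column name) and to 8275160 and 9402422 in the trained control libraries (eGFP.250 and eGFP.266). They came to 6537749 and 272456 in the untrained knockdown libraries (KD.253 and KD.255) and to 8541894 and 1484318 in the trained knockdown libraries (KD.249 and KD.251). A single read was worth 15.6 normalized counts in library KD.255 and 2.88 in library KD.251, against 0.444 to 0.659 in the other 6 libraries. A floor of 3 reads, the most that a count of 0 allows, corresponded to 46.7 normalized counts in library KD.255 and 8.65 in library KD.251, against at most 1.98 elsewhere. Reads carried no molecular identifiers, so such floors and the intervals given with read ratios (95%) cover counting error only. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 25.0 (untrained control), 34.0 (trained control), 2.08 (untrained knockdown) and 9.60 (trained knockdown), and each was counted as 1 sample.

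The main test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(normalized read count + 1), for the 12681 genes with a mean of at least 10 over the 8 libraries. All 4 groups shared 1 estimate of the spread (4 residual degrees of freedom, 5.13 added by the prior). Fold changes are on this scale, which mostly understates the change of genes with few reads. The shallow library KD.255 is an exception. A count of 0 there enters as 0 although up to 46.7 normalized counts are possible, so a drop in knockdown mice can be overstated. The sterol genes Idi1 and Stard4 had 0 reads in that library. There were 7 comparisons: training within each vector, the knockdown vector against the control vector within each training state, the difference of the training responses (interaction), and training and knockdown each averaged over the other factor in an additive model. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run beside it on the recovered reads. The design assumed a normalized unit or raw counts, and the deposited unit called for limma as the main test.

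Before the data were examined, 32 gene lists were fixed from textbook knowledge, and 30 with at least 5 tested members were tested with camera (limma), adjusted over the 30 lists of a comparison, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. They covered neuronal activity (immediate early and delayed activity genes), glucocorticoid response, acetyl-CoA metabolism, sterol and SREBP targets, histone acetyltransferases, histone deacetylases, glutamate receptors, synaptic genes, unfolded protein and heat shock genes, interferon response, antigen presentation, DNA damage and p53 response, respiratory chain, ribosomal protein genes and nuclear-retained RNAs. Markers of pyramidal and granule neurons, inhibitory neurons, astrocytes, reactive glia, microglia, oligodendrocytes, their precursors, endothelium, choroid plexus, ependyma, meninges, thalamus, neocortex and striatum made up the rest. The list of blood cell markers had 1 tested gene and the list of mitochondrially encoded genes had 0 in the table, so neither was tested. The comparisons, the rule for genes named in the text and most alternatives were also set before the data were examined. That rule took Acss2, then per comparison up to 10 genes in each direction with the largest change among those that passed and whose groups of libraries did not overlap. Where fewer passed, the genes with the smallest unadjusted p filled up to 5 per direction. It also took up to 6 members of each reported list by p, and 10 fixed immediate early genes whatever their values.

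Alternatives changed the pseudocount, the filter, the scaling (TMM, quantile), the trend, the prior, the threshold, the groups in the fit, the tool, or left out each library in turn. A further 6 kinds were added after the data were seen: DESeq2, leaving out the 2 shallow knockdown libraries, keeping only the 6 libraries with the lower numbers (up to KD.255), library quality weights, thinning to the shallowest library with edgeR, and a term for 2 sets of libraries. The quality weights came out equal within each group (0.481 for both KD.253 and KD.255), so they could not weigh a shallow library against its partner. The steps were tested on simulated reads with 200 of 12681 genes changed. With limma, changes of 2-, 4- and 8-fold were recovered in 31.3%, 88.1% and 93.9% of genes for the averaged knockdown comparison, in 7.46%, 68.7% and 89.4% for training in control-vector mice, and in 0%, 28.4% and 62.1% for the interaction. A simulated list of 30 genes raised 2-fold was called in all 7 comparisons with either correlation, and 0 of 29 unchanged lists were called. Simulated genes were drawn independently of each other, so the simulation could not test whether the preset correlation is high enough. In the data, for training in control-vector mice, the estimated correlation was 0.263 for immediate early genes and 0.00247 for acetyl-CoA metabolism. Gene positions were taken by symbol from the GENCODE vM21 annotation of GRCm38 (the mm10 build), which held 23607 of the 24498 symbols. Python 3.11.15 and matplotlib 3.10.9 drew the figures.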

Results

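The study crossed the vector (ACSS2 knockdown or EGFP control) with spatial object training (trained or home cage) in the mouse dorsal hippocampus, and polyadenylated RNA was sequenced from 2 libraries in each of the 4 groups. ACSS2 is the enzyme that makes acetyl-CoA from acetate, and acetyl-CoA is the acetyl donor for histone acetylation. Reads in genes numbered between 6537749 and 9863728 in 6 libraries, against 1484318 in the trained knockdown library KD.251 and 272456 in the untrained knockdown library KD.255. Pairs of libraries correlated with a Spearman coefficient between 0.919 and 0.981 across genes. The highest coefficient, 0.981, joined KD.253 and KD.249 of different groups, against 0.933 to 0.971 for the pairs within a group. The first principal component held 28.7% and the second 27.8% of the variance. Neither separated the vectors or the training states, and the second set KD.255 (-34.8) apart from the rest.

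The targeted gene, Acss2 (GRCm38, chromosome 2, 155517948 to 155585724, plus strand, protein coding), was lower in all 4 knockdown libraries than in any control library. Its normalized read count was 58.2 and 82.0 in the untrained control libraries (eGFP.254 and eGFP.268) and 87.4 and 67.5 in the trained control libraries (eGFP.250 and eGFP.266). In knockdown mice it was 25.0 and 15.6 without training (KD.253 and KD.255) and 25.6 and 57.7 with training (KD.249 and KD.251). The value in library KD.255 was 1 read, so at this depth it set only an upper range. Control libraries averaged 73.8 ± 13.4 (SD, n = 4) and knockdown libraries 31.0 ± 18.4 (SD, n = 4), a ratio of 0.420. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries can give. The full separation behind it rests on 57.7 in KD.251 (20 reads) against 58.2 in eGFP.254 (100 reads), and on 1 read in KD.255. It is therefore not firm. Among all genes tested with limma, the log2 difference of -1.37 (SE 0.33) did not pass (adjusted p = 0.333), nor did those of -1.76 (SE 0.47) in untrained and -0.98 (SE 0.47) in trained mice (adjusted p = 0.798 and 1.00). It passed without library KD.251, whose Acss2 value lay near the controls (-1.67, adjusted p = 0.0433).

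The first comparison asked what the knockdown vector changed whatever the training. Interferon-stimulated genes rose in the knockdown libraries. Ccl5, a T-cell attracting chemokine (chromosome 11, 83525778 to 83530518), stood at 114 normalized counts against 3.19 in controls, a log2 difference of 4.84 (SE 0.37, n = 4 against 4, limma adjusted p = 0.00213). Ifit3, an antiviral protein with tetratricopeptide repeats (chromosome 19, 34583531 to 34588731), rose from 33.1 to 670, or by 4.21 (SE 0.40, adjusted p = 0.00866). The related Ifit1, Ifit2 and Ifit3b rose by 4.34 (SE 0.54), 2.85 (SE 0.38) and 3.90 (SE 0.48). Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481), went from 7.15 to 151 (3.96, SE 0.48, adjusted p = 0.021). Ddx60 and Oasl2, which act against viruses, rose by 4.18 and 4.21, and Rsad2, with the same role, from 5.46 to 107. Trim30a rose by 3.31. The chemokine Cxcl10 (chromosome 5, 92346638 to 92348889) rose by 5.15 (SE 0.72, adjusted p = 0.0336), from a control mean of 1.28 near the read floor. Its call was lost with 2 sets of libraries as a term. H2-D1, a class I histocompatibility heavy chain (chromosome 17, 35262730 to 35267499), went from 31.4 to 159 (2.25, SE 0.28, adjusted p = 0.021). Slfn8, which the naming rule did not take for this comparison, completed the 13 genes that passed, all higher in knockdown. The Ifit, histocompatibility and Slfn genes belong to families of similar sequence, so the split of reads among their members is uncertain.

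**Figure D1:**
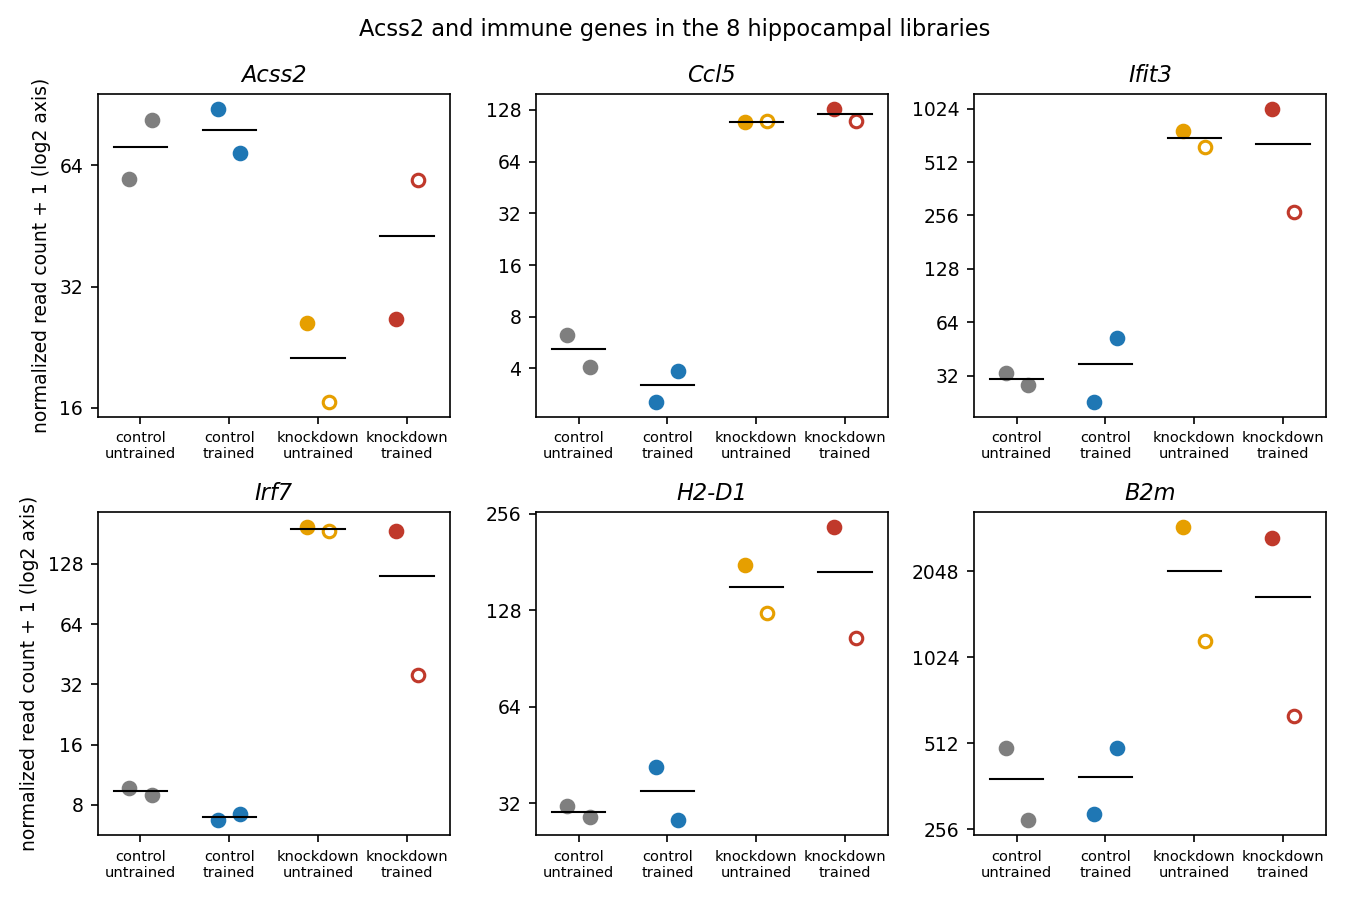
Normalized read count plus 1 (log2 axis) of Acss2, Ccl5, Ifit3, Irf7, H2-D1 and B2m in each of the 8 libraries by group, with points for libraries, open circles for the 2 shallow knockdown libraries (KD.255 and KD.251) and black lines for group means. Acss2 lies lower in the knockdown groups, and Irf7 reaches 34.6 in library KD.251 against 186 to 195 in the other 3 knockdown libraries.

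By edgeR 122 genes passed in this comparison (116 higher, 6 lower) and by DESeq2 195 (165 higher, 30 lower), and the 13 genes passed with both. Ccl5 alone of the 13 kept its call without library eGFP.268 or without library eGFP.250. Without library eGFP.254, KD.253 or KD.249, 2 of the 13 kept it, and without library eGFP.266, 9 did. Leaving out library KD.251, in which Irf7 (34.6) lay between controls and the other knockdown libraries, raised the count to 100 genes. Leaving out both shallow knockdown libraries raised it to 212, and with only the 6 libraries with the lower numbers (up to KD.255) it was 0 (Ccl5 4.84, adjusted p = 0.0672).

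All 28 tested members of the interferon response list were higher in knockdown mice, with a median log2 difference of 3.08; 8 passed over all genes and 26 adjusted over the list alone. Relative to the control mean of each gene, the list's median was between -0.37 and 0.33 in control libraries and 3.93, 3.06, 3.95 and 1.46 in knockdown libraries KD.253, KD.255, KD.249 and KD.251. The list passed camera with the preset correlation (adjusted p = 2.7e-57) but not with an estimated one (adjusted p = 0.12 with an estimated correlation). A pass with the preset correlation was common. Of 30 lists, 17 passed for the averaged knockdown, 11 for it in untrained and 17 in trained mice. For training, 14 passed in control-vector mice, 6 in knockdown mice and 14 averaged, and 8 for the interaction. With an estimated correlation 0 passed in each comparison. The antigen presentation list was higher in 14 of 14 members (median 2.09; 1 passed over all genes, 9 adjusted over the list alone; camera adjusted p = 5.9e-16, adjusted p = 0.181 with an estimated correlation). In it, B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), had means of 1851 and 386, a difference of 2.06 (SE 0.46) with adjusted p = 0.242 by limma, 0.0175 by edgeR and 0.0110 by limma with 2 sets of libraries as a term. H2-K1 differed by 2.12, and Nlrc5, the transactivator of class I genes, by 2.81 (limma adjusted p = 0.337 and 0.216, edgeR 0.00901 and 0.00258).

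Reactive glia and microglia lists were higher as well. The reactive glia list had 16 of 19 members higher and a median of 1.11 (1 passed over all genes, 11 adjusted over the list alone), with values of 2.18 (SE 0.46) for complement C4b, 1.42 (SE 0.24) for the protease Ctss and 1.33 (SE 0.23) for the cytokine receptor Osmr, none of which passed limma over all genes. All 21 microglia markers were higher, with a median of 0.65 (0 passed over all genes, 10 adjusted over the list alone), with 1.54 for complement C1qa and 0.65 for the receptor Csf1r. Camera gave adjusted p = 4.5e-16 and 2.1e-16 for these lists with the preset correlation, and adjusted p = 0.181 and 0.12 with an estimated correlation. In library KD.251 the microglia median was 0.18 above controls, against 0.70 to 0.88 in the other knockdown libraries.

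Sterol and SREBP target genes were lower, in 26 of 29 members by count of signs, with a median of -0.52 (0 passed over all genes, 2 lower adjusted over the list alone; camera adjusted p = 1.7e-10, adjusted p = 0.181 with an estimated correlation). The squalene synthase Fdft1 differed by -0.78 (SE 0.16) and the squalene epoxidase Sqle by -0.93 (SE 0.29); limma passed neither, and edgeR gave Fdft1 an adjusted p of 0.0413. Library KD.251 again stood apart, at 0.06 relative to controls against -0.57 to -0.87 in the other knockdown libraries. Oligodendrocyte markers were higher (18 of 19, median 0.34, camera adjusted p = 5.3e-08, adjusted p = 0.282 with an estimated correlation; 1 adjusted over the list alone), with the iron carrier Trf at 0.86 (SE 0.18) and the myelin-associated Ermn at 0.56. The per-library medians of these markers overlapped between vectors (exact permutation p = 0.4). Besides Acss2 and list members, low values were those of Reep6 (-1.14), Ankrd24 (-1.09), the proline transporter Slc6a7 (-0.90, SE 0.18) and Aifm3 (-0.75, SE 0.13). None passed limma, and edgeR called Slc6a7 and Aifm3 (adjusted p = 0.0252 and 0.0275).

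Within untrained mice, the knockdown comparison asked what the vector changed at rest. Ccl5 averaged 108 ± 1.02 in knockdown and 4.17 ± 1.51 in control libraries (SD, n = 2 each), a log2 difference of 4.43 (SE 0.54). The value in KD.255 was only 7 reads, so the small SD of the knockdown pair does not show close agreement. Ifit3 differed by 4.50, Irf7 by 4.36, Slfn8 by 3.69 and the helicase Ddx60 by 4.64. With limma 0 genes passed, with 571 at an unadjusted p under 0.05 against 634 expected by chance, and the smallest adjusted p was 0.168, for Ccl5. edgeR called 23 genes, all higher, among them these 5 (adjusted p between 0.0020 and 0.0363), and DESeq2 called 55. With 2 sets of libraries as a term edgeR called 74. The interferon list had a median of 3.55, with 28 of 28 members higher and 27 passing adjusted over the list alone. The antigen presentation median was 2.24 (8 adjusted over the list alone), reactive glia 1.46 (9), microglia 0.70 (6), oligodendrocyte markers 0.52 (1) and immediate early genes 0.44 (4). Fos, without passing, averaged 114 and 26.7 (limma adjusted p = 0.461), with only 9 reads in KD.255. Sterol targets stood at -0.62 and pyramidal and granule neuron markers at -0.49, with 0 passing adjusted over the list alone in either. Camera passed all 8 lists with the preset correlation (adjusted p from 1.2e-47 for interferon response to 1.5e-04 for the neuron markers) and 0 with an estimated one (adjusted p = 0.268 with an estimated correlation for 7 of them and 0.287 for sterol targets). The lower neuron markers and higher microglia and oligodendrocyte markers accompanied the interferon genes in these untrained libraries. Without library KD.253 the sterol list no longer passed (-0.44, adjusted p = 0.0723), nor did the neuron markers (-0.42, adjusted p = 0.095). Besides Acss2 and list members, low values were those of Scube1 (-1.25), Tunar (-1.18), Gnb5 (-0.94), Aifm3 (-0.83) and Thy1, a neuronal surface glycoprotein (-0.82), none of which passed. With 2 libraries against 2, an exact test could not go below p = 0.333.

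Within trained mice, Ccl5 rose from 2.21 ± 0.93 to 119 ± 13.7 (SD, n = 2 each), by 5.25 (SE 0.54, limma adjusted p = 0.0499), and was the 1 gene that passed, with 299 genes at an unadjusted p under 0.05. The call was lost without library eGFP.254, eGFP.268, eGFP.250, eGFP.266, KD.249 or KD.251 (largest adjusted p = 1.00), while the difference stayed between 4.95 and 5.55, and 11 other genes passed without library KD.251. edgeR called 4 genes, among them Ccl5 (adjusted p = 3.6e-04), Ifit3 (3.93, adjusted p = 0.0474) and the antiviral Rsad2 (4.01, adjusted p = 0.0474), and DESeq2 called 33. With 2 sets of libraries as a term edgeR called 70. H2-D1 differed by 2.19 and Ifit3b by 3.63 without passing either limma or edgeR. The lists moved as in untrained mice for interferon response (median 2.58, 28 of 28 higher, 20 adjusted over the list alone), antigen presentation (1.64, 1), reactive glia (0.75, 6), microglia (0.55, 21 of 21 higher, 0) and sterol targets (-0.48, 0). All 5 passed camera with the preset correlation (adjusted p between 2.1e-45 and 1.0e-07), and adjusted p was 0.159 for interferon and microglia, 0.256 for reactive glia and 0.259 for the other pair with an estimated correlation. Without library KD.249 the medians of antigen presentation (0.72, adjusted p = 0.105), reactive glia (0.24, adjusted p = 0.0742) and sterol targets (-0.05, adjusted p = 0.494) no longer passed. Immediate early genes were higher here too (0.25, 27 of 34, adjusted p = 0.0148, adjusted p = 0.461 with an estimated correlation), but did not pass without library eGFP.250 (0.19) and stood at -0.066 without library KD.249. Oligodendrocyte markers did not pass (0.12, 13 of 19 higher, adjusted p = 0.0682), and stood at -0.081 without library KD.251 and at 0.40 without library KD.249. Pyramidal and granule neuron markers were higher here (0.11, 20 of 30, adjusted p = 0.0292, adjusted p = 0.346 with an estimated correlation), opposite to untrained mice. They did not pass without library eGFP.250 (0.065, adjusted p = 0.454) and stood at -0.11 without library KD.251. Choroid plexus markers were lower (-2.46, adjusted p = 1.8e-06, adjusted p = 0.401 with an estimated correlation), and stood at 0.16 without library eGFP.250. Among lower genes, none passing limma or edgeR, were Rhov (-3.25), the imprinted Nnat (-1.59), Pdzrn3 (-1.32), Prrg3 (-1.29) and Slc6a7 (-1.18). DESeq2 called Rhov (adjusted p = 0.0464).

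Training in control-vector mice asked what 30 min after spatial object exploration does to hippocampal RNA. Each of the 10 immediate early genes fixed in advance had higher values in both trained libraries than in both untrained ones, without passing limma. The transcription factor Egr2 (chromosome 10, 67535475 to 67542188) averaged 72.2 ± 14.9 against 9.59 ± 2.89 (SD, n = 2 each), a log2 difference of 2.80 (SE 0.54). Fos (chromosome 12, 85473890 to 85477273) averaged 117 ± 19.4 against 26.7 ± 15.8, a difference of 2.21 (SE 0.43), and Arc, a synaptic regulator of receptor trafficking (chromosome 15, 74669083 to 74672570), 1027 ± 108 against 397 ± 178 (1.44, SE 0.30). Fosb differed by 1.63 (SE 0.33), Egr1 by 1.00, Junb by 0.92, Nr4a2 by 0.77, the phosphatase Dusp1 by 0.74, Nr4a1 by 0.69 and the neuron-specific Npas4 (chromosome 19, 4984355 to 4990316) by 0.47. The immediate early list had 31 of 34 members higher and a median of 0.63 (0 passed over all genes, 4 adjusted over the list alone; camera adjusted p = 1.4e-17, adjusted p = 0.182 with an estimated correlation). No single gene passed limma (adjusted p = 1.00 for all those named), with 181 genes at an unadjusted p under 0.05 against 634 expected by chance. edgeR also called 0 genes (7 with 2 sets of libraries as a term, chosen after the data were seen), and DESeq2 called 4, among them Egr2 (2.92, adjusted p = 0.0016), Fos (2.15, adjusted p = 0.015) and Arc (1.37, adjusted p = 0.024). Leaving out library eGFP.268, the untrained library with the lowest Fos and Arc values, brought Fos to 1.60, Arc to 0.97, Junb to 0.55, Egr1 to 0.49, Npas4 to 0.30, Nr4a1 to 0.18 and Dusp1 to 0.068.

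**Figure D2:**
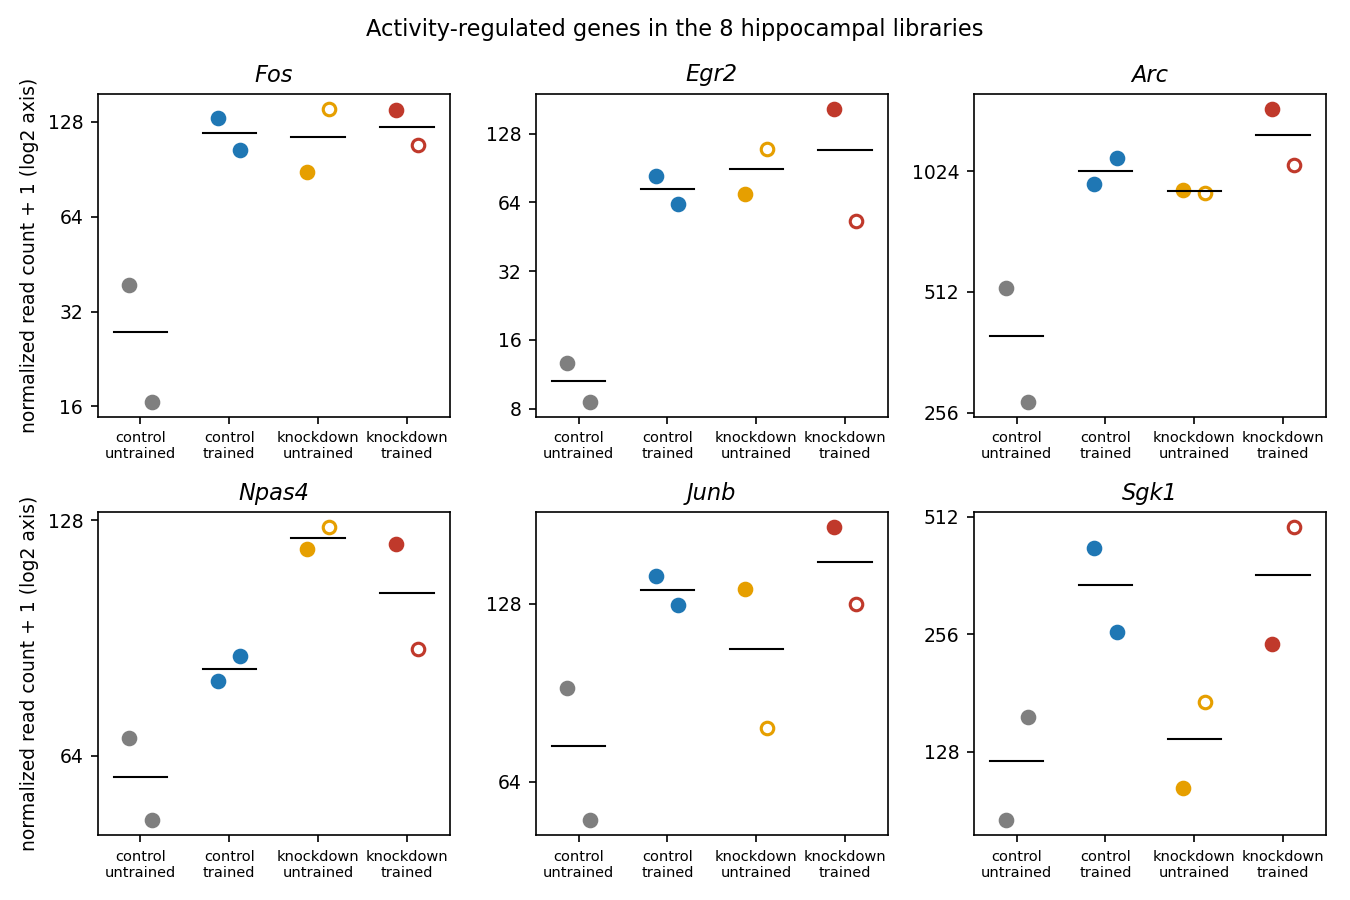
Normalized read count plus 1 (log2 axis) of Fos, Egr2, Arc, Npas4, Junb and Sgk1 in each of the 8 libraries by group, with points for libraries, open circles for the 2 shallow knockdown libraries (KD.255 and KD.251) and black lines for group means. Fos averaged 26.7 in untrained control, 117 in trained control, 114 in untrained knockdown and 123 in trained knockdown libraries.

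Oligodendrocyte markers were also higher after training in control-vector mice, in 19 of 19 members with a median of 0.70 (6 adjusted over the list alone; camera adjusted p = 1.9e-19, adjusted p = 0.182 with an estimated correlation). Among them, Mobp differed by 1.13, Trf by 1.09 (SE 0.24) and Ermn by 0.91. The per-library medians of this list were -0.08 and -0.62 without training (eGFP.254 and eGFP.268) and 0.22 and 0.56 with it. Unfolded protein and heat shock genes were higher in 21 of 22 members (median 0.31, camera adjusted p = 1.5e-06, adjusted p = 0.182 with an estimated correlation), with the chaperones Pdia4 at 0.62 and Creld2 at 0.72. Glucocorticoid-response genes had a median of 0.56 (camera adjusted p = 1.6e-04, adjusted p = 0.182 with an estimated correlation), with the kinase Sgk1 (chromosome 10, 21882184 to 21999903) at 1.52 (SE 0.44) and Pdk4 at 1.04, and lost its call without library eGFP.268 (0.35, adjusted p = 0.0814). Pyramidal and granule neuron markers were lower, with a median of -0.30 (24 of 30 negative, 1 lower adjusted over the list alone; camera adjusted p = 1.9e-06, adjusted p = 0.182 with an estimated correlation). Without library eGFP.268, Mobp was at 0.72, Creld2 at 0.47 and Mpped1 at -0.45, and without library eGFP.250 Pdia4 was at 0.38 and Neurod1 at -0.26. Fibcd1, a marker of CA1 neurons, read 99.3 and 117 with training and 223 and 279 without, a difference of -1.20 (SE 0.25), with Mpped1 at -0.72 and Neurod1 at -0.52. Other low values were those of Syt17 (-1.14), Glis3 (-1.07), the glycerol-3-phosphate dehydrogenase Gpd1 (-0.78) and Wasf1 (-0.63), none of which passed.

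Markers of tissue next to the hippocampus moved between these libraries too. Ependymal markers had a median of 1.26 (camera adjusted p = 1.2e-06, adjusted p = 0.335 with an estimated correlation) that no longer passed without library eGFP.268 (0.31, adjusted p = 0.231) or library eGFP.250 (0.61, adjusted p = 0.064). Thalamus markers had a median of 0.40 (adjusted p = 7.1e-04, adjusted p = 0.211 with an estimated correlation), and did not pass without library eGFP.268 (0.30) or library eGFP.250 (0.14). Choroid plexus markers had a median of 1.34 (adjusted p = 0.00311, adjusted p = 0.652 with an estimated correlation), which turned to -0.36 without library eGFP.268 and to -1.15 without library eGFP.250. The choroid plexus transcript Ttr read 15080 in library eGFP.254, 57479 in library eGFP.250 and between 133 and 1768 in the other 6.

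Training in knockdown mice asked for the same response under the knockdown vector. Fos averaged 123 ± 22.6 with and 114 ± 37.0 without training (SD, n = 2 each), a log2 difference of 0.13 (SE 0.43), and Egr2 differed by 0.10 (SE 0.54). In the untrained library KD.255, Fos had only 9 reads and Egr2 only 7. Fosb differed by 0.77 (SE 0.33), Junb by 0.52, Arc by 0.45 (SE 0.30), Nr4a2 by 0.32, Egr1 by 0.18, Nr4a1 by -0.06, Npas4 by -0.25 and Dusp1 by -0.48. Without single libraries Fosb ranged from 0.34 to 1.19 and Arc from 0.22 to 0.69, both lowest without library KD.249. Egr3, of the same zinc finger family, stood at 0.88 (SE 0.21) and Sgk1 at 1.36 (SE 0.44). The immediate early list had 26 of 34 members higher and a median of 0.27, which did not pass (camera adjusted p = 0.0773) but passed without library KD.251 (0.57, adjusted p = 4.6e-04), and also passed with 2 sets of libraries as a term. limma called 0 genes (568 at an unadjusted p under 0.05, 634 expected by chance, smallest adjusted p = 0.802), and edgeR and DESeq2 called 0 each. Other named values were those of Zfp189 (1.13), Kansl1l (1.06), Ap1s2 (0.97), the collagen prolyl hydroxylase P4ha1 (0.90), Rhov (-3.07), Tox (-1.87), Sox12 (-1.15), Parm1 (-0.97) and fibronectin, Fn1 (-0.90), none of which passed.

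Several lists passed camera after training in knockdown mice. Endothelial and mural markers were lower (median -0.38, 19 of 21 negative, adjusted p = 0.00625, adjusted p = 0.356 with an estimated correlation), with the tight junction gene Cldn5 at -1.02 and the receptor Kdr at -0.79, and did not pass without library KD.253 (-0.47, adjusted p = 0.312). Glucocorticoid-response genes (0.30) and ribosomal protein genes (0.27) were higher, both at adjusted p = 0.0166, with adjusted p = 0.538 and 0.356 with an estimated correlation. Neither passed without library KD.253 (adjusted p = 0.718 and 0.842), nor did the first without library KD.251 (adjusted p = 0.0802). The interferon list stood at -0.70 (adjusted p = 8.9e-05, adjusted p = 0.845 with an estimated correlation), a value that turned to 0.41 without library KD.251 and to 0.12 without both shallow libraries. Microglia markers (-0.26, adjusted p = 0.0102) and sterol targets (0.37, adjusted p = 0.0166), each at adjusted p = 0.845 with an estimated correlation, came to -0.05 and -0.12 without library KD.251.

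The interaction asked whether the training response differed between vectors. The difference (knockdown minus control) was -2.71 (SE 0.77) for Egr2, -2.08 (SE 0.61) for Fos, -1.22 for Dusp1, -0.99 (SE 0.43) for Arc, -0.86 for Fosb, -0.82 for Egr1, -0.75 for Nr4a1, -0.72 for Npas4, -0.45 for Nr4a2 and -0.39 for Junb. Without library eGFP.268, Dusp1 was at -0.55, Arc at -0.52, Egr1 at -0.31, Nr4a2 at -0.27, Nr4a1 at -0.24 and Junb at -0.022, and without library KD.251 Fosb was at -0.43. Without both shallow libraries Egr2 was at -1.56 and Npas4 at -0.45. No gene passed limma (adjusted p = 1.00 for those named, 112 at an unadjusted p under 0.05), edgeR or DESeq2, with 0 calls each. The immediate early list had 24 of 34 members lower and a median of -0.44 (0 adjusted over the list alone; camera adjusted p = 3.1e-04, adjusted p = 0.702 with an estimated correlation). The call was lost without library eGFP.268 (-0.13, adjusted p = 0.166) or library KD.253 (-0.04, adjusted p = 0.412), as well as without library KD.251 (-0.19) and with only the 6 libraries with the lower numbers (up to KD.255) (-0.10, adjusted p = 0.270). Untrained knockdown libraries already had higher immediate early values than untrained controls (median 0.44, above), so the level before training enters this difference. Pyramidal and granule neuron markers differed the other way (0.56, camera adjusted p = 3.7e-06, adjusted p = 0.464 with an estimated correlation), with C1ql2 at 1.90 and Lct at 1.58, and no longer passed without library KD.253 (adjusted p = 0.0672). Oligodendrocyte markers were lower in 19 of 19 members (-0.48, adjusted p = 5.0e-06, adjusted p = 0.641 with an estimated correlation) and lost the call without library eGFP.268 (-0.19), KD.253 (-0.39) or KD.249 (-0.30). Other named values were those of Rhov (-3.66), Pdzrn3 (-1.41), the citron kinase Cit (-0.98), Pde8b (0.90), Rfx3 (1.14), Sema5a (1.34), Glis3 (1.43) and Capn3 (1.86). Without both shallow libraries Lct was at 0.80, C1ql2 at 1.11, Pde8b at 0.59, Rfx3 at 0.73, Sema5a at 0.77, Glis3 at 0.94 and Capn3 at 1.17.

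Averaged over vectors, training compared 4 trained with 4 untrained libraries. Sgk1, a serum- and glucocorticoid-induced kinase, averaged 352 and 128 in trained and untrained libraries, a log2 difference of 1.44 (SE 0.30) with higher values in 4 of 4 trained libraries than in any untrained one. Fosb differed by 1.20 (SE 0.26), Trf by 0.82, P4ha1 by 0.75 and the splicing kinase Clk1 by 0.54. Lower values were those of Rtn4rl2 (-1.18), Fibcd1 (-0.88, SE 0.19), Sema6b (-0.81), Sez6 (-0.69) and Gprin1 (-0.54). limma passed 0 genes (adjusted p = 0.873 for those named, 616 at an unadjusted p under 0.05), edgeR 0 and DESeq2 12, among them Sgk1 (1.52, adjusted p = 0.0017) and Fosb (adjusted p = 0.0039). Sgk1 also passed limma with 2 sets of libraries as a term (adjusted p = 0.0155), an alternative chosen after the data were seen. Those sets were the split that called most genes here, and Sgk1 was itself among the 63 genes called between them (-0.83, limma adjusted p = 0.0380). Its pass with that term is therefore not separate support. Immediate early genes had a median of 0.52 (31 of 34 higher, 1 adjusted over the list alone; camera adjusted p = 1.5e-08) and oligodendrocyte markers 0.46 (18 of 19, 6; adjusted p = 1.5e-08), each at adjusted p = 0.32 with an estimated correlation. Ependymal markers (1.10, adjusted p = 1.6e-04) and glucocorticoid-response genes (0.29, adjusted p = 1.6e-04, 1 adjusted over the list alone) were higher, at adjusted p = 0.366 and 0.171 with an estimated correlation. Microglia markers were lower (-0.23, adjusted p = 9.5e-04, adjusted p = 0.32 with an estimated correlation, 1 lower adjusted over the list alone).

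**Figure D3:**
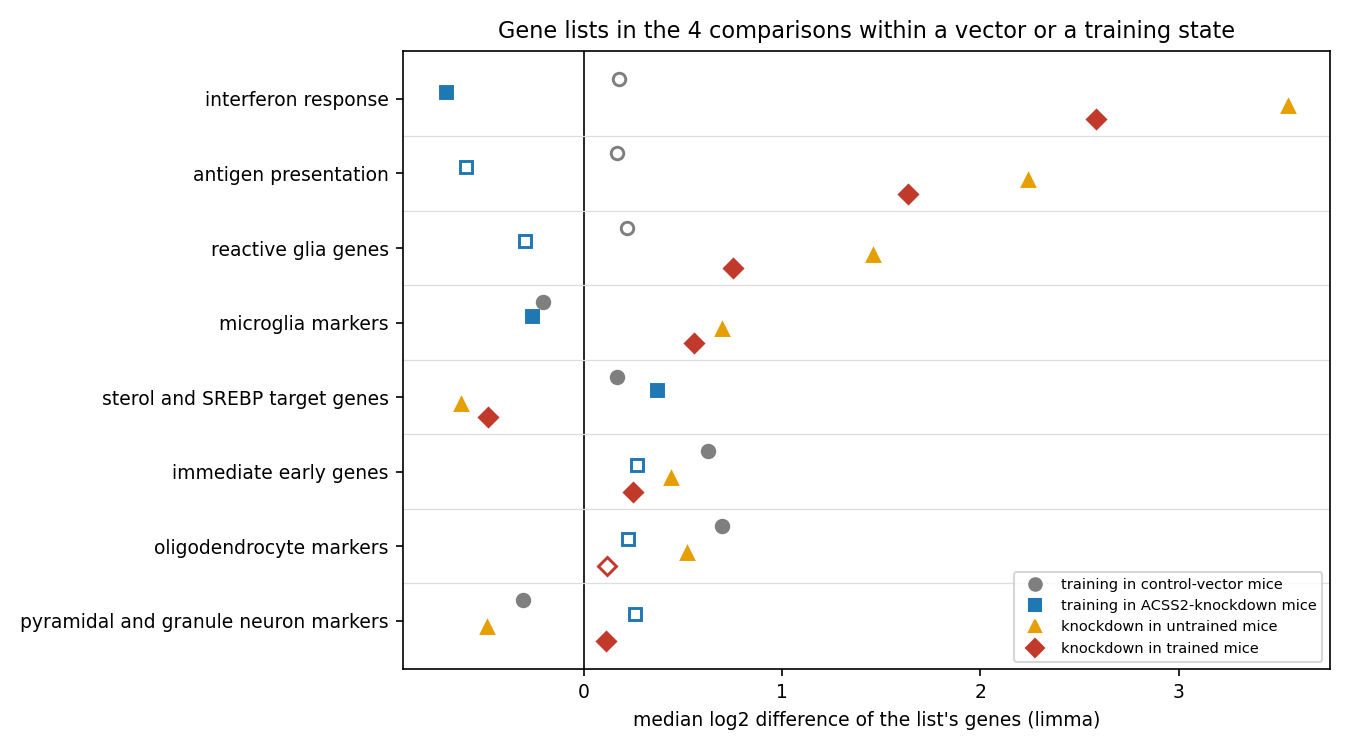
Median log2 difference of 8 gene lists (vertical) in the training comparisons within each vector and the knockdown comparisons within each training state, with filled points for lists that passed camera (adjusted p under 0.05, preset correlation) and open points for those that did not. The interferon list reaches 3.55 and 2.58 in the knockdown comparisons, and the immediate early list 0.63 and 0.27 in the training comparisons.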

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

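Medians of 5 lists and 4 hormone values stood apart within an arm of 4 libraries, and 8 list medians differed between vectors in their training response, none of them with an estimated correlation (smallest adjusted p = 0.464). The tests of low depth and of microglia for the interferon genes, those of the untrained control library and of neuron share for the immediate early genes, and that of the pituitary genes with few reads elsewhere were chosen only after the result was seen. Of 70 groups of 4 libraries tested for a library far from the other 3, 9 had one, against 3.5 expected by chance. Of the 9, 4 came from hormones entered by name. Among these, Gh and Prl had 0 reads in most libraries, where any library with reads stands apart by construction. The excess over 3.5 therefore does not show that outlying libraries were more common than by chance.

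Pituitary hormone transcripts stood far above the other control libraries in the trained control library eGFP.250. Growth hormone, Gh, read 956 there, prolactin, Prl, 85.8 and the hormone precursor Pomc 813, against 1.74 to 2.39 for Pomc in the other 3 control libraries. Gh also stood apart in knockdown library KD.249, at 1.02, which was 2 reads.

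The list medians, given relative to the control mean of each gene, had 1 library far from the other 3 of its vector in 5 cases. These were synaptic genes in eGFP.250 (-0.11, low), pyramidal and granule neuron markers in KD.251 (0.16, high), inhibitory neuron markers in KD.249 (-0.49, low), oligodendrocyte markers in KD.251 (0.69, high) and nuclear-retained RNAs in KD.255 (-0.17, high).

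The training response differed between vectors, by camera on the interaction with the preset correlation, for 8 lists. Medians were -0.44 for immediate early genes, 0.56 for pyramidal and granule neuron markers, -0.48 for oligodendrocyte markers, -0.88 for interferon response, -0.60 for meningeal markers, -0.41 for thalamus markers, -0.17 for neocortex markers and -0.27 for unfolded protein and heat shock genes. With an estimated correlation none passed (adjusted p = 0.464 to 0.702). The interferon value came to 0.21 without library KD.251, and the meningeal value to 0.04 without library eGFP.268. The calls for thalamus, neocortex and unfolded protein genes were also lost without library eGFP.268 (adjusted p = 0.201, 0.201 and 0.118).

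For the interferon genes that rose with the knockdown vector, low depth of libraries KD.255 and KD.251 did not account for the rise. The list's median was 3.99 (3.16 to 4.83) in the 2 deep knockdown libraries against the 4 control libraries. Ranges of list medians, here and below, are the median plus or minus its SE, from the spread of per-library medians pooled within groups. A larger share of microglia accounts for too little, since microglia markers differed by 0.646 (0.503 to 0.789). T-cell genes chosen apart from the list had 2.41 times (2.07 to 2.79) the share of reads of controls in the deep knockdown libraries, which fits some T-cell RNA in the tissue. In library KD.251, however, T-cell reads (10.1 RPM, reads scaled by depth) lay within the controls (9.67 to 10.7 RPM) while interferon reads were at 493 RPM against 174 to 236. At the depth of KD.251 no T-cell gene had more than 5 reads, so a modest rise of T-cell RNA there is not excluded. Loss of ACSS2 and the hairpin cassette itself cannot be told apart, because 0 control libraries carried a vector with a hairpin.

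For the immediate early genes, whose interaction median was below 0 but passed only with the preset correlation, 1 low untrained control library could not be excluded as the cause. Without the untrained control library that moved the interaction more, its median was -0.133 (-0.523 to 0.257). Neuron markers were lower after training in control mice, at -0.305 (-0.478 to -0.132), which points away from a larger share of neurons as the cause of the rise there. This range spans only the SE on either side, so a larger share of neurons is not excluded. Without the 2 shallow knockdown libraries the interaction median was -0.419 (-0.846 to 0.00818), which leaves low depth open. Loss of ACSS2 may also act here, and the interaction does not separate a smaller response from a higher level before training.

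For the hormones in library eGFP.250, 14 pituitary genes with few reads in other control libraries had 171 times (86.0 to 399) the share of reads of those libraries, which fits carry-over of pituitary tissue. A test fixed earlier on 16 pituitary genes gave 1.39 (1.33 to 1.45) and cannot tell, because Pcsk1n and Scg5, also abundant in hippocampus, held 6959 of the 6967 reads outside this library. Hypothalamus genes had 8.83 times (6.98 to 11.2) that share, a ratio that fits carry-over of hypothalamus as well. It came mainly from Trh and Cartpt (135 and 62 of 267 reads in eGFP.250). Hdc, Nkx2-1, Gal, Sim1 and Otp had between 5 and 22 reads there. Avp, Oxt, Hcrt, Pmch, Agrp, Ghrh and Kiss1 had between 0 and 3, so most of the list does not bear on hypothalamus as a source. No biological explanation was tested, because the second trained control library did not share the hormone reads.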

How the results depend on the processing

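DESeq2, leaving out the 2 shallow knockdown libraries or those with the higher numbers, thinning, quality weights and a term for 2 sets of libraries were tests chosen only after the result was seen. Results for named genes kept direction and side of the threshold in 3093 of 3345 alternatives (100 weaker, 138 stronger, 14 reversed), and lists in 1390 of 1594 (169 weaker, 15 stronger, 20 reversed). Counts stayed within 1.5 times in 126 of 172, and Acss2 kept its side in 70 of 74. Most named gene results, and all of those for Acss2, did not pass in the main fit. For these, keeping the side meant staying without a call. Changes of the trend, the prior or the threshold also leave a fold change as it is, so these tallies do not measure how firm a call is. No paired analysis was possible because the columns carry no replicate number that links them to the samples of the labels, so the planned block was not run. Leaving out 1 library leaves a lone sample in its group, which is assumed to vary like the other groups. Depth limits genes with under 46.7 normalized counts, 3 reads in library KD.255. Unless stated, the cause was not tested.

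Genes called for the averaged knockdown numbered 25 with quantile scaling, 1 with no trend, 122 with edgeR, 212 without the shallow libraries, 0 with only the lower library numbers, 20 with 2 sets as a term, 66 with thinned reads and 195 with DESeq2. In trained mice the knockdown count was 0 with pseudocount 0.5, no filter, the stricter filter or only the groups compared, 4 with edgeR, 79 without the shallow libraries, 4 with 2 sets as a term, 5 thinned and 33 with DESeq2. In untrained mice it was 1 with pseudocount 5 or quantile scaling, 24 with only the groups compared, 23 with edgeR, 67 without the shallow libraries, 6 with 2 sets as a term, 12 thinned and 55 with DESeq2. Averaged training had 1 with 2 sets as a term, 1 thinned and 12 with DESeq2, and training in control-vector mice 4 with DESeq2. Leaving out single libraries gave 1 to 100 for the averaged knockdown, 0 to 11 in trained and 0 to 1293 in untrained mice, 0 to 1242 for training in knockdown mice and 0 to 710 for the interaction. The last 3 maxima came without KD.253, which leaves only the shallowest library, KD.255, in its group.

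Acss2, knockdown averaged over training, passed without the shallow libraries (-1.49) and with DESeq2 (-1.27), and ranged from -1.67 to -1.16 without single libraries (in untrained mice -2.08 to -1.43, the lowest without KD.253, which leaves 1 Acss2 read in that group and so does not bear on the knockdown). In trained mice Acss2 ranged from -1.55 without KD.251 to -0.41 without KD.249. The list immediate early genes, interaction, stood at -0.44 with an estimated correlation, -0.10 with only the lower numbers and -0.64 to -0.040 without single libraries (adjusted p = 0.0525 without KD.251). In training of knockdown mice it passed at 0.24 (quantile), 0.27 (only the groups compared, the lower numbers, or 2 sets as a term), 0.21 (edgeR) and 0.29 (without the shallow libraries), and ranged from 0.019 to 0.57. With an estimated correlation it was 0.63 for training in control-vector mice, and the interferon list was 3.08, 2.58 and 3.55 for the knockdown averaged, in trained and in untrained mice, none passing.

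Directions turned with thinned reads for gene Dusp1, training in control-vector mice (-0.00702; interaction and training in knockdown mice both 0.15), Gnb5 (0.045, knockdown untrained) and Pdk4 (-0.70, training in control-vector mice). Without the shallow libraries they turned for Npas4 (0.019) and interferon (0.12) in training of knockdown mice, for oligodendrocyte markers (-0.081, knockdown in trained mice) and for histone deacetylases (0.056, knockdown averaged). Glutamate receptors, knockdown averaged, turned with no filter (-0.022, by the direction of the test), the lower numbers (0.021) and quality weights (0.017). Without single libraries, ranges in training of knockdown mice were -0.10 to 0.46 for Egr1, -0.72 to 0.91 for Egr2, -0.20 to 0.47 for Fos, -0.31 to 0.19 for Nr4a1, -2.10 to 0.41 for interferon and -0.12 to 0.64 for sterol targets. For choroid plexus they were -1.15 to 4.16 (training in control-vector mice) and -5.04 to 0.16 (knockdown in trained mice), in the latter also -0.066 to 0.46 for immediate early genes and -0.081 to 0.40 for oligodendrocyte markers, and for interferon in the interaction -2.04 to 0.21. For the averaged knockdown they were -0.055 to 0.077 for glutamate receptors, -0.14 to 0.00472 for histone deacetylases and -0.11 to 0.10 for oligodendrocyte precursors.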

Other observations

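The tests of 2 sets of libraries, as groups and as a term, were chosen only after the result was seen, while the gene lists were fixed before the data were examined. With the knockdown vector, averaged over training, acetyl-CoA metabolism genes were lower in 27 of 33 members (median -0.19, camera adjusted p = 0.00219, adjusted p = 0.12 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Acot7, an acyl-CoA thioesterase, stood at -0.39 and the citrate carrier Slc25a1 at -0.48. Respiratory chain genes were lower in 38 of 40 members (-0.21, adjusted p = 3.0e-05, adjusted p = 0.285 with an estimated correlation). Immediate early genes (median 0.28, 30 of 34 higher, adjusted p = 5.3e-08) and delayed activity genes (0.15, 25 of 37 higher, adjusted p = 0.00219) were higher, with adjusted p = 0.282 and 0.139 with an estimated correlation. Among these, Nptx2, a neuronal pentraxin, was at 0.90, Homer1 at 0.45 and the neurotrophin Bdnf at 0.40, none passing. The p53 response list had a median of 0.01 and passed as higher (adjusted p = 0.0266, adjusted p = 0.282 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.36 (SE 0.35) the 1 gene passing adjusted over the list alone. It did not pass without library eGFP.268, eGFP.266 or KD.253 (adjusted p = 0.110, 0.105 and 0.174). With thinned reads neither the acetyl-CoA list (-0.14) nor the delayed list (0.07) passed.

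Choroid plexus markers (-2.07, adjusted p = 1.2e-05), meningeal markers (-0.65, adjusted p = 0.00589), neocortex markers (-0.35, adjusted p = 0.0106), synaptic genes (-0.12, adjusted p = 0.0115), nuclear-retained RNAs (-0.29, adjusted p = 0.0228) and inhibitory neuron markers (-0.19, adjusted p = 0.0308) were also lower in knockdown libraries. With an estimated correlation the adjusted p was 0.357, 0.333, 0.282, 0.282, 0.181 and 0.481. The choroid medians were 1.13 and 3.43 in control libraries eGFP.254 and eGFP.250, but -2.76 and -1.93 in eGFP.268 and eGFP.266, within the -3.48 to -1.27 of knockdown libraries (exact permutation p = 0.2). Each of the other lists lost the call without at least 1 library: meningeal, neocortex and nuclear-retained without eGFP.250 (adjusted p = 0.103, 0.0689 and 0.103), synaptic without KD.253 (adjusted p = 0.118) and inhibitory without KD.249 (adjusted p = 0.449). The synaptic genes Syp and Stx1a stood at -0.40 and -0.59. Among the 13 lists that did not pass were histone acetyltransferases (median 0.05, adjusted p = 0.161), histone deacetylases (-0.09, adjusted p = 0.454), glutamate receptors (-0.02, adjusted p = 0.906), astrocyte markers (0.01, adjusted p = 0.214), oligodendrocyte precursor markers (-0.01, adjusted p = 0.712, with the test pointing up) and striatum markers (-0.12, adjusted p = 0.213).

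Across the 6989 genes with a mean of at least 100 normalized counts, the training differences in the vectors correlated with r = 0.162 (Spearman 0.185). The knockdown differences in trained and untrained mice correlated with r = 0.385 (Spearman 0.183), with no library shared within a pair and genes not independent of each other.

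For the averaged knockdown count, chance could not be excluded. Of 34 splits of the libraries into 4 and 4, the real one included, 2 called at least its 13 genes. The other of these called 122, and every remaining split called 0. The verdict thus rests on that 1 split, described below, which may not be a chance draw, so the test cannot decide. For averaged training the count of splits tells nothing, since the real split called 0 genes and so all 34 called at least as many, the highest 98. The same other split stood highest in both and points to a structure of the samples that the labels do not give: eGFP.254, eGFP.266, KD.253 and KD.249 against the other 4, 1 library of each group on each side. The share of reads in no gene was at most 17.9% in the first set and at least 18.5% in the other, which holds both shallow libraries. What lies behind the sets was not tested. Between these sets limma called 63 genes (41 lower in the first set, 22 higher), among them, chosen after their values were seen, Rpl15 (-1.24), Rps21 (-1.85) and Uqcrh (1.05), and 7 of 47 ribosomal protein genes. With the sets as a term the knockdown count by limma was 20 genes (17 higher, 3 lower), 12 of the 13 among them. Those added included B2m (2.06, adjusted p = 0.0110) and the 3 lower genes Abat (-0.88), Dnm3 (-0.87) and 2900052N01Rik (-0.96). The call of gene Cxcl10, knockdown averaged over training, was lost (adjusted p = 0.0534). The averaged training count was 1, Sgk1, which was itself among the 63 genes called between the sets. By edgeR with this term the counts were 149 for the averaged knockdown, 74 in untrained and 70 in trained mice, 7 for training in control-vector mice and 0 for training in knockdown mice and for the interaction.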
